A study of Mus musculus with 46 samples.

How the data were processed

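The data are RNA-seq measurements of glial progenitor cells sorted from the striatum of mice, a forebrain region that degenerates in Huntington disease. Per the labels' protocols, the mice carried an EGFP reporter of the progenitor receptor PDGFRA, the subventricular zone was removed, and the striata of a litter were pooled by genotype. Pools held 3 to 4 mice, or 4 to 8 mice at 1 year. The tissue was dissociated with papain and freed of myelin and debris on Percoll, and EGFP-positive cells that excluded DAPI were collected by fluorescence-activated sorting. RNA was purified on RNeasy columns, and libraries were made with the TruSeq RNA v2 kit, which selects polyadenylated RNA and does not record the strand. They were sequenced with paired-end reads on an Illumina HiSeq instrument, per the series' design text.

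The authors deposited 1 table of expected counts per gene, which need not be whole numbers because RSEM shares reads that match several genes. Per the submitters' processing notes, the tools were CASAVA, STAR 2.5.2b and RSEM 1.3.0. The notes name a human genome build, although all gene identifiers in the table are those of mouse genes. The mouse build and annotation release behind the counts are therefore not given in the sources used here. All 46 columns were matched to a library by name. The table holds 53801 genes, and 9.4% of its values were not whole. Gene symbols, types and positions were taken from GENCODE release M21 on build GRCm38, in which 53620 of the identifiers were found and 181 were not; 94 identifiers shared a symbol with another and were kept apart by their identifier. Positions printed are those of that annotation, not of the authors' files.

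Libraries were grouped by genotype, line and age as the labels give them, into 8 groups of 4 to 7 pools. Each library is a pool of different mice of a litter, so the spread between libraries includes biological differences. Total expected counts per library lay between 23338185 and 49166260. No pair of libraries of a group was a duplicate: the smallest chi-square per degree of freedom between any such pair was 20.5. The labels give no sequencing batch, so a batch that follows age or line cannot be separated from it. In both 12-week groups of the R6/2 line 74.6 to 78.0% of the values above 0 were whole, against 69.0 to 74.5% in the other libraries. The libraries of those groups therefore differed from the rest in a property that the labels do not describe.

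Expected counts were rounded to whole numbers. For each comparison genes were filtered with filterByExpr and scaled by TMM, and edgeR 4.0.16 (R 4.3.3) was used to fit a robust quasi-likelihood model. Only the groups compared entered each fit, 2 for a simple contrast and 4 for an interaction. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Adjusted p values for single genes are from this test unless another tool is named, log2 fold changes are given with their standard error (SE), and levels are given as TMM-scaled CPM, counts relative to a common library size, with their standard deviation (SD) between pools. The 4 genotype comparisons, 3 interactions, 2 age comparisons in wild-type mice, 1 overlap and 28 gene lists, their members included, were fixed before the data were examined.

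The lists cover cholesterol synthesis enzymes, sterol regulation, fatty acid synthesis, myelin sphingolipid synthesis, mature oligodendrocyte and myelin genes, committed and premyelinating oligodendrocyte genes, progenitor genes, Wnt pathway genes, cell cycle genes, glutamate and GABA receptors, potassium channels, extracellular matrix and adhesion, stress responses, interferon-stimulated genes, immediate early genes, mitochondrially encoded mRNAs, Hox genes, sex-specific transcripts, and markers of striatal projection neurons, neurons in general, neuroblasts, astrocytes, microglia, endothelium, mural cells, fibroblasts, ependyma and red blood cells. A list was tested with camera (limma 3.58.1) when at least 3 members passed the filter, with the preset correlation of 0.01 between genes, and p values were adjusted over the lists. Camera with an estimated correlation and fry were run beside it. By fry 5 and 20 lists passed for R6/2 at 6 and 12 weeks, and 0 and 0 for zQ175 at 12 weeks and 1 year. For the age differences of R6/2 and zQ175 14 and 0 passed, and 17 for the line difference. For wild-type age in the R6/2 and zQ175 lines 4 and 14 passed. Some lists that did not pass with an estimated correlation passed fry, such as the progenitor list in the R6/2 age difference (fry adjusted p = 0.0322). Counts of members past the threshold are given over all genes tested and, where it differs, "adjusted over the list alone". Fewer than 3 Hox genes passed the filter in any of the 4 genotype comparisons, so that list was not tested there.

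Genes named in the text follow a rule also fixed before the data were examined. In the genotype comparisons it takes the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 2 and a gene name that is not a clone name, up to 4 called members of each list with the smallest p, and 10 genes fixed by name, of which Htt, Pdgfra, Tcf7l2, Myrf, Sox10, Olig2, Mbp and Hmgcs1 are given. For the interactions and age comparisons it takes 4 genes in each direction, up to 3 per list, and Tcf7l2, Pdgfra and Htt. Others of the 10 fixed genes that are given for an interaction outside this rule were chosen after their values were seen. Results of some genes that the rule takes are not reported here, not every other gene of the rule is printed, and any gene outside it is said to have been chosen after its values were seen.

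The procedure was tested on simulated data made from the real libraries' means and sizes, with 200 genes changed and the interferon list raised 2-fold besides. Counts were drawn for each gene independently, so the correlation between genes in the real pools was not simulated. In the 6-week R6/2 design the procedure called 56.2% of the 2-fold and 17% of the 1.5-fold changes among the 200 genes. In the 12-week R6/2 design it called 61.9% and 36.8%. In the 12-week zQ175 design it called 70.1% and 36.1%, and in the 1-year zQ175 design 16.7% and 1%. The biological coefficient of variation was 41.5%, 30.2%, 31.2% and 58.3% in these comparisons, in the same order, so changes at 1 year were measured least precisely.

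Alternatives tried were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0 and limma voom with quality weights as other tests, the replicate number as a block, all 8 groups in 1 fit, 1 surrogate variable (sva 3.50.0), Y-linked transcripts as a covariate, an adjusted p below 0.01, no genes of chromosomes 5, X and Y, and each library left out in turn. A fit without libraries that stand apart and one with markers of other cell types as a covariate were added after the data were seen. Each comparison was repeated on 100 splits of its libraries, the real one included. Python 3.11.15 was used to join the tables and draw the figures.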

Results

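The study profiled RNA from PDGFRA-EGFP-positive glial progenitor cells of the striatum in 2 mouse lines of Huntington disease and their wild-type littermates. R6/2 mice carry a short fragment of the human huntingtin gene with an expanded CAG repeat and fall ill early, while zQ175 mice carry the expansion in their own Htt gene and progress slowly. The series title names suppressed remyelination that responds to TCF7L2, a transcription factor of oligodendrocyte differentiation. The R6/2 line was sampled at 6 weeks (6 R6/2 and 5 wild-type pools) and at 12 weeks (7 and 7 pools). The zQ175 line was sampled at 12 weeks (6 and 6 pools) and at 1 year (5 and 4 pools). Total expected counts per library were 34943456 to 48634226 in the 6-week groups and 33337839 to 49166260 in the 12-week groups of the R6/2 line. They were 29409075 to 42447698 in the 12-week groups and 23338185 to 35458137 in the 1-year groups of the zQ175 line.

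The sorted cells expressed myelin genes at very high levels in all 8 groups. In 6-week wild-type pools Mbp, which encodes the protein that compacts myelin (chromosome 18, 82475146 to 82585637), was measured at 13100 ± 844 CPM (SD, n = 5). The receptor gene of the reporter, Pdgfra (chromosome 5, 75152292 to 75198215), was measured at 56.5 ± 24.9 CPM in the same pools. Pdgfra was lower, and more variable on the log2 scale, in wild-type pools of the zQ175 line, at 11.1 ± 9.31 CPM (SD, n = 6) at 12 weeks and 4.91 ± 7.5 CPM (SD, n = 4) at 1 year. Between lines these levels were not tested, and line cannot be separated from batch. Pdgfra did not pass the main test in any of the 4 genotype comparisons.

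Mouse Htt (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534), the gene altered in zQ175 mice, served as a check of the labels. At 12 weeks it was 2.42-fold lower in zQ175 pools, with 5.1 ± 1.93 CPM (SD, n = 6) against 12.1 ± 2.13 CPM (SD, n = 6) and no overlap between the groups (log2 fold change -1.27 ± 0.22, adjusted p = 0.0412). At 1 year its log2 fold change was -1.33 ± 0.56, with 5.7 ± 5.04 CPM (SD, n = 5) against 15 ± 7.59 CPM (SD, n = 4), and it did not pass the test (adjusted p = 0.393), nor without zQ175 replicate 5 (-2.02, adjusted p = 0.119). The 12-week call was kept in 1 of the 12 fits that left out 1 library, with an adjusted p of up to 0.117, and was lost with all 8 groups in 1 fit (adjusted p = 0.227). These p values are adjusted over all genes tested. In the main edgeR fits the unadjusted p of Htt was 2.57e-05 at 12 weeks and 0.033 at 1 year. R6/2 mice carry a human fragment, which mouse Htt does not measure, and their Htt log2 fold change was 0.38 ± 0.29 at 6 weeks and 0.13 ± 0.19 at 12 weeks, neither past the test.

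The 6-week comparison of R6/2 and wild-type pools asked what differed in these cells early in the course of the faster model. Myelin genes were lower and interferon-stimulated genes were higher in R6/2. Mbp was 1.48-fold lower, with 8820 ± 628 CPM (SD, n = 6) against 13100 ± 844 CPM (SD, n = 5). Usp18, a negative regulator of interferon signalling, was 8.25-fold higher, with 18.2 ± 7.39 against 2.21 ± 1.25 CPM. In all, 695 of 14913 genes were called, 347 higher and 348 lower in R6/2, of which 151 and 25 differed at least 2-fold.

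Of 24 mature oligodendrocyte and myelin genes, 18 fell, none rose (1 adjusted over the list alone) and 6 did not pass, and the list passed camera (adjusted p = 4.2e-26, and adjusted p = 0.00923 with an estimated correlation). Car2, the cytosolic carbonic anhydrase of oligodendrocytes, fell by 1.12 on the log2 scale (adjusted p = 7.59e-06), and Qdpr, which regenerates tetrahydrobiopterin, fell by 0.73 (adjusted p = 0.000318). Myrf, the transcription factor that switches on myelin genes, fell by 0.44 ± 0.08 (adjusted p = 0.0108), and Olig2, which specifies the lineage, fell by 0.49 ± 0.10 (adjusted p = 0.0174). The Olig2 call was lost without wild-type replicate 3 or 6 (adjusted p of up to 0.0512). Sox10 and Tcf7l2 did not pass, with log2 fold changes of 0.04 ± 0.08 and 0.13 ± 0.18. Of 20 committed and premyelinating genes, 1 rose (2 adjusted over the list alone) and 1 fell, and of 22 progenitor genes, none rose and 1 fell (camera adjusted p = 0.982 and 0.609).

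Lipid synthesis genes were lower in part. Of 20 cholesterol synthesis enzymes, 3 fell (9 adjusted over the list alone) and none rose: Idi1 fell by 0.70, Msmo1 by 0.59 and Dhcr7, the enzyme of the last step to cholesterol, by 0.56. The Dhcr7 call was lost without wild-type replicate 2 (adjusted p = 0.0586), and that of Msmo1 in 5 of 11 fits that left out 1 library. Of 11 genes of myelin sphingolipid synthesis, 3 fell (5 adjusted over the list alone), among them Ugt8a, which makes galactosylceramide, by 0.90, and Fa2h, which hydroxylates its fatty acid, by 0.70. Of 18 fatty acid synthesis genes, 3 fell (6 adjusted over the list alone) and 1 rose. These lists passed camera with the preset correlation (adjusted p = 1.51e-06, 0.00169 and 0.0156) but not with an estimated correlation (adjusted p = 0.441, 0.406 and 0.511).

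Of 15 interferon-stimulated genes, 9 rose (12 adjusted over the list alone) and none fell, and the list passed camera (adjusted p = 2.55e-18, and adjusted p = 0.0324 with an estimated correlation). Irf9, a subunit of the transcription factor that answers type I interferon, was 3.76-fold higher (adjusted p = 0.000352), and Rtp4 and Oasl2 were 5.36-fold and 11.4-fold higher. Among the largest rises, Gbp6 and Irgm1, both interferon-inducible GTPases, were 68-fold and 7.13-fold higher, although wild-type pools held only 0.135 ± 0.221 CPM of Gbp6 (SD, n = 5). Col9a2, a collagen chain, was 11.2-fold higher, with 41.4 ± 8.39 against 3.68 ± 1.48 CPM. The largest falls included Il33, an alarmin cytokine of the interleukin-1 family, which was 3.12-fold lower, with 166 ± 25.9 against 521 ± 158 CPM. None of 15 microglia and macrophage, 14 endothelial, 11 mural or 16 astrocyte markers passed the test in these libraries. The 13 fibroblast markers had a median log2 fold change of -0.39 with none called (camera adjusted p = 0.0156, but adjusted p = 0.757 with an estimated correlation). The 10 neuroblast markers had a positive median of 0.88, with 1 called (camera adjusted p = 0.0117, but adjusted p = 0.406 with an estimated correlation). It was Tubb3, a neuronal tubulin that is also on the pan-neuronal list, with a log2 fold change of 1.00 ± 0.24 (adjusted p = 0.0308), a call lost in 7 of 11 fits that left out 1 library. Of 13 markers of striatal projection neurons, Arpp21 rose and Adcy5 fell, with log2 fold changes of 1.75 and -0.80 (adjusted p = 0.00709 and 0.003), and neither that list nor the pan-neuronal one passed camera (adjusted p = 0.979 and 0.389).

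The count of 695 calls fell to 452 and 451 without R6/2 replicate 3 or 4 and to 449 and 461 without wild-type replicate 2 or 6. It was 1268 with DESeq2, 1163 with limma voom and 1363 with 1 surrogate variable, and 691, 681 and 695 of the 695 genes were among these.

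The 12-week comparison of R6/2 asked the same at an age when the mice are severely ill. Myelin and cholesterol synthesis genes were lower and interferon-stimulated genes higher, and many genes of oligodendrocyte progenitors were higher. Mbp was 1.83-fold lower in R6/2, with 6220 ± 476 CPM (SD, n = 7) against 11000 ± 409 CPM (SD, n = 7). Bcan, a proteoglycan of the progenitor surface, was 6.86-fold higher, with 735 ± 68 against 103 ± 33.6 CPM, and Ifit1, an interferon-induced antiviral gene, was 31.2-fold higher, with 70.4 ± 16.5 against 2.18 ± 1.7 CPM. In all, 5704 of 14952 genes were called, 2848 higher and 2856 lower, of which 1479 and 813 differed at least 2-fold.

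Of 24 mature oligodendrocyte and myelin genes, 22 fell and 2 did not pass, and the list's median log2 fold change was -0.99 (camera adjusted p = 2.6e-32, and adjusted p = 0.0104 with an estimated correlation). Mal, a proteolipid of myelin membranes, was 3.61-fold lower, and Mobp was 2.83-fold lower. Among the regulators of the lineage, Myrf fell by 0.73 ± 0.12, Sox10 by 0.45 ± 0.10 and Olig2 by 0.32 ± 0.08 (adjusted p = 0.000165, 0.00161 and 0.00313). Tcf7l2 (chromosome 19, 55741820 to 55933654) was 1.32-fold higher, with 30 ± 3.92 against 21.9 ± 4.29 CPM (SD, n = 7 each; adjusted p = 0.0186). Its log2 fold change no longer passed with Y-linked transcripts as a covariate (0.33, adjusted p = 0.165) or with markers of other cell types as one (0.21, adjusted p = 0.48).

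Of 20 cholesterol synthesis enzymes, 15 fell and none rose (camera adjusted p = 4.92e-09, and adjusted p = 0.0121 with an estimated correlation). Cyp51, which demethylates lanosterol, was 2.61-fold lower, Dhcr7 was 2.3-fold lower, and Hmgcs1, an early enzyme of the pathway, was 1.9-fold lower, with 188 ± 15.2 against 345 ± 48.1 CPM (SD, n = 7 each). Of 18 genes of sterol regulation, uptake and export, 4 rose and 4 fell (camera adjusted p = 0.596): Insig1, a sterol-responsive brake on synthesis, was 2.2-fold lower, and Abca1, which exports cholesterol, was 1.92-fold higher. Of 11 sphingolipid genes, 7 fell and 1 rose, with Fa2h 3.23-fold and Ugt8a 3.05-fold lower, and of 18 fatty acid genes, 11 fell and 2 rose. These lists passed with the preset correlation (adjusted p = 6.55e-06 and 0.00104) but not with an estimated correlation (adjusted p = 0.0848 and 0.398).

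Of 16 interferon-stimulated genes, 14 rose and none fell (camera adjusted p = 8.1e-18, and adjusted p = 0.0104 with an estimated correlation). Oasl2 and Irf9 were 22.1-fold and 9.91-fold higher. Of 22 progenitor genes, 15 rose, 3 fell and 4 did not pass, with a median log2 fold change of 1.47, but the list's call (adjusted p = 3.8e-06) was lost with an estimated correlation (adjusted p = 0.405). Sox6 and Serpine2 were 5.66-fold and 4.88-fold higher, while Olig2 and Sox10 were among those that fell, and Pdgfra did not pass (67.9 ± 22.8 against 76.4 ± 27.1 CPM; log2 fold change -0.23 ± 0.27). Of 20 committed and premyelinating genes, 8 rose and 6 fell (7 adjusted over the list alone; camera adjusted p = 0.395): Neu4 and Bmp4, a growth factor that opposes oligodendrocyte maturation, were 5.05-fold and 4.99-fold higher, and Nkx6-2 was 1.8-fold lower. Of 28 extracellular matrix and adhesion genes, 17 rose and 4 fell (adjusted p = 6.63e-05, but adjusted p = 0.42 with an estimated correlation), among them Nlgn1, a postsynaptic adhesion gene, at 2.98-fold higher.

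Markers of fibroblasts, microglia and vascular cells were lower in the same R6/2 pools. Of 13 fibroblast markers, 11 fell, among them Col1a1, a fibrillar collagen, by 2.17 ± 0.23. Of 16 microglia markers 6 fell (Cx3cr1, the fractalkine receptor, by 1.59), of 14 endothelial markers 6 fell (Kdr, a VEGF receptor, by 1.44), and of 11 mural markers 4 fell (Pdgfrb by 1.60), with no marker of these lists higher. Adjusted over the list alone, 12, 8, 7 and 5 fell. Their median log2 fold changes were -1.57, -0.95, -1.12 and -0.81 in that order (camera adjusted p = 7.57e-06, 0.0304, 0.0303 and 0.0415; with an estimated correlation adjusted p = 0.398, 0.628, 0.561 and 0.462). Of 16 astrocyte markers, 3 rose and 8 fell (9 adjusted over the list alone; camera adjusted p = 0.395), and of 5 red blood cell genes, 4 fell (adjusted p = 0.0556). The pools also differed in sex: 4 of 7 R6/2 pools and 0 of 7 wild-type pools had Y-linked transcripts at or below 1 CPM, and 2 of 7 wild-type pools had Xist at or below that level.

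The largest rises were genes hardly detected in wild-type pools, such as Tecta, at 7.61 ± 2.69 against 0.0268 ± 0.0478 CPM, and Reln, a secreted guidance protein, at 12 ± 4.63 against 0.222 ± 0.19 CPM (SD, n = 7 each). The largest fall was that of Il33, 6.2-fold lower, at 258 ± 85.1 against 1550 ± 155 CPM, and the receptor gene Kit was 5.35-fold lower. R6/2 replicate 7 had the highest mitochondrial share of its group, at 2.72%, and 7025 genes were called without it.

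**Figure D1:**
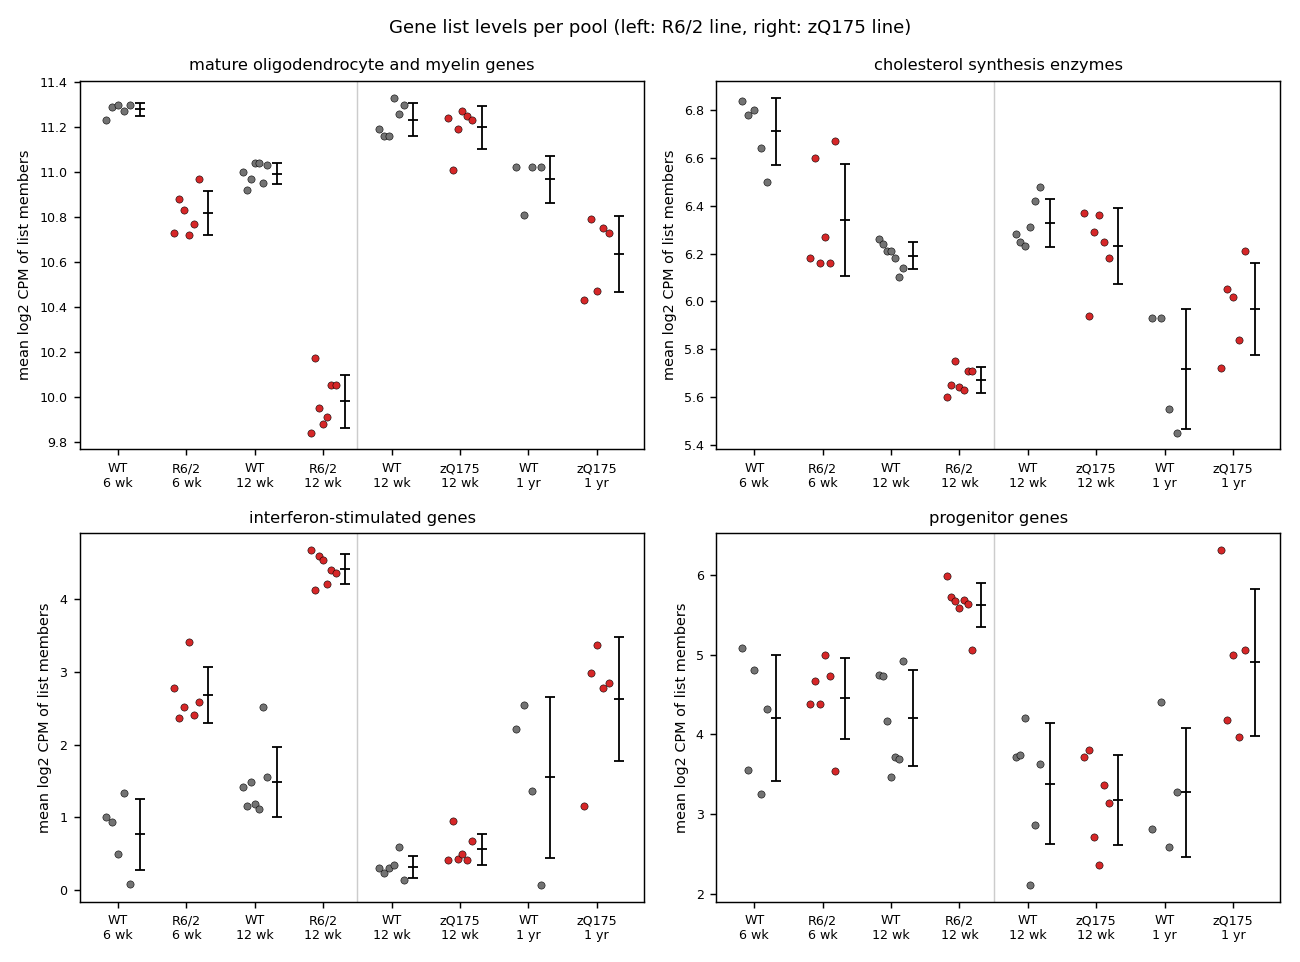
Mean log2 CPM of the members of 4 gene lists in each library (points), by group, with the group mean and SD; each panel has its own axis. The mature oligodendrocyte and myelin list averaged 9.98 ± 0.12 in 12-week R6/2 pools against 10.99 ± 0.05 in their wild type, and the interferon list 4.41 ± 0.2 against 1.49 ± 0.48.

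Between 6 and 12 weeks the R6/2 effect on myelin genes grew. The age-by-genotype interaction was past the threshold for 996 of 16513 genes, 470 in the positive and 526 in the negative direction. On the log2 scale it was -0.29 ± 0.08 for Mbp (adjusted p = 0.0382) and -0.48 ± 0.13 for Sox10 (adjusted p = 0.026), which had not passed at 6 weeks. Both were fixed by name for the genotype comparisons only, and were chosen here after their values were seen. Of the same fixed genes, Myrf, Olig2 and Hmgcs1 did not pass, at -0.28 ± 0.16, 0.18 ± 0.12 and -0.19 ± 0.21 (adjusted p = 0.361, 0.461 and 0.692). Of 24 mature genes, 19 (21 adjusted over the list alone) had a more negative effect at 12 weeks (camera adjusted p = 1.59e-24, and adjusted p = 0.0046 with an estimated correlation). Mal, Opalin and Mog, 3 myelin membrane genes, had interactions of -1.01, -1.08 and -0.65.

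Irf9 and Ifit3, interferon-stimulated genes, had positive interactions of 1.41 and 2.13, and 4 of 16 genes of that list passed (7 adjusted over the list alone). Bcan and Bmp4 had interactions of 1.92 and 1.66, and Vat1l and Plce1, a phospholipase, of 3.94 and 3.85. Immediate early genes, which tissue dissociation also induces, moved in the same direction. Of 18 such genes 7 passed (9 adjusted over the list alone), among them Jun at 0.97 and Junb at 1.67. That list passed camera with the preset correlation (adjusted p = 7.09e-07) but not with an estimated one (adjusted p = 0.189). The interferon and progenitor lists passed with the preset correlation (adjusted p = 2.4e-05 and 3.61e-08) but not with an estimated one (adjusted p = 0.198 and 0.221). Tcf7l2 had an interaction of 0.28 ± 0.22, Pdgfra of 0.27 ± 0.44 and Htt of -0.25 ± 0.35, none past the test. Markers of other cell types had negative medians, -1.21 for 14 endothelial markers with none called and -1.09 for 13 fibroblast markers with 3 called (4 and 4 adjusted over the list alone). Both lists passed with the preset correlation (adjusted p = 0.000579 and 5.01e-06) but not with an estimated one (adjusted p = 0.279 and 0.221). In all, 14 lists passed with the preset correlation, 5 in the positive and 9 in the negative direction, and 1 of them, the mature myelin list, with an estimated one. The count was 1784 without R6/2 12-week replicate 7, 1864 with limma voom, 434 with all 8 groups in 1 fit and 638 with markers of other cell types as a covariate.

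The calls at the 2 ages overlapped. Of the genes tested at both ages, 290 were higher and 328 lower in R6/2 at both, where 64.8 and 68.6 would be shared by independent lists, and 3 went in opposite directions. The comparisons share no library. Across genes the log2 fold changes correlated with Pearson's r = 0.57 and Spearman's rho = 0.52, although genes are not independent replicates.

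**Figure D2:**
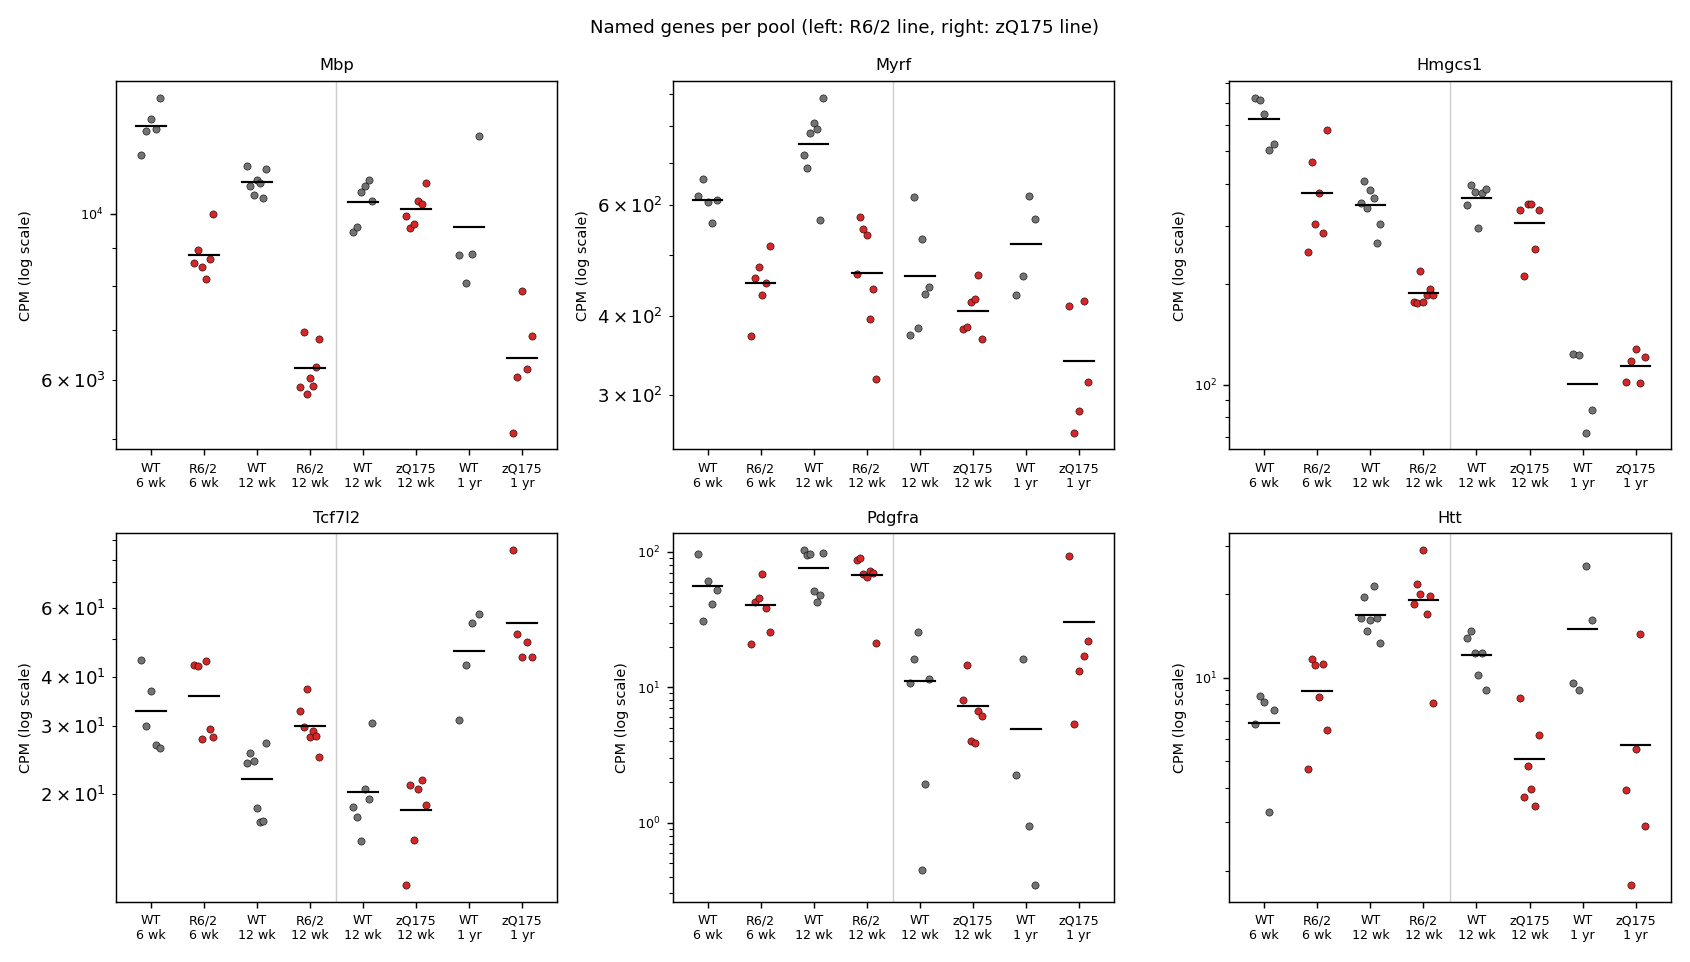
CPM of 6 named genes in each library (points) with group means (lines), on logarithmic axes. Mbp was lower in R6/2 than in wild-type pools at 6 and 12 weeks, and Htt was lower in 12-week zQ175 pools, at 5.1 against 12.1 CPM.

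The 12-week comparison of zQ175 asked what differed in the slower model at the age of the severe R6/2 stage. Of 14374 genes, 12 were called, 7 higher and 5 lower in zQ175 (2144 had an unadjusted p below 0.05). Apart from Htt, 5 genes within 20 Mb of it on chromosome 5 were called, where 0.19 would be by chance (Fisher's exact test, two-sided p = 5.64e-07). They were Slc35f6, a solute carrier, which fell by 0.68 ± 0.09 (adjusted p = 0.00381), and a cluster of 4 genes between positions 25956626 and 26105362, 5031410I06Rik, Gm5067, Gm6089 and Gm21168, with log2 fold changes of 4.78, 1.33, 2.27 and 1.26. The cluster genes have clone names and were chosen after their values were seen. Other genes tested between these positions were not called and went both ways. They ranged from -0.78 ± 0.34 for Gm21680 to 1.46 ± 0.43 for Gm10471, also chosen after their values were seen. Gm5067, Gm6089 and Gm21168 are annotated as processed pseudogenes, and reads shared with near-identical copies make their values uncertain. The 4 cluster genes are neighbours and not independent draws, so the p of 5.64e-07 is too small. With genes less than 1 Mb apart counted once, 2 of 8 called places lay within 20 Mb of Htt (Fisher's exact test, two-sided p = 0.00728).

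The calls beyond that window were Dnmt3a, a DNA methyltransferase, which fell by 0.62 ± 0.10 (adjusted p = 0.0366), Prkdc, a kinase of DNA repair, which fell by 0.68 ± 0.12 (adjusted p = 0.0435), Hectd4, also on chromosome 5, which fell by 0.69 ± 0.12 (adjusted p = 0.0488), Olfm1 and Rpl13a, which were 1.55-fold and 1.39-fold higher (adjusted p = 0.0435 and 0.0412), and Gm11361, chosen after its values were seen. Of these named genes, Slc35f6 kept its call in all 12 fits that left out 1 library, and Hectd4 in none, while Dnmt3a and Rpl13a kept theirs in 2 and Olfm1 and Prkdc in 1. The edgeR count was 5 or 4 without zQ175 replicate 2, 4, 5 or 6 or wild-type replicate 2, 3, 4 or 6, 34 with Y-linked transcripts as a covariate, and 0 without chromosomes 5, X and Y, where 1924 genes had an unadjusted p below 0.05. It was 442 with DESeq2, among them 11 of the 12 genes, and 12 with limma voom.

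No myelin, progenitor or interferon gene of the lists was called at 12 weeks in zQ175. Mbp had a log2 fold change of -0.06 ± 0.07, with 10200 ± 532 against 10400 ± 692 CPM (SD, n = 6 each), Myrf of -0.22 ± 0.12 and Tcf7l2 of -0.18 ± 0.18. The list that passed was fatty acid synthesis and desaturation, with 16 of 17 members at negative log2 fold changes and 5 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.000159, but adjusted p = 0.848 with an estimated correlation). Cholesterol enzymes had a median of -0.10 (adjusted p = 0.103), and none of the lists of other cell types passed.

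**Figure D3:**
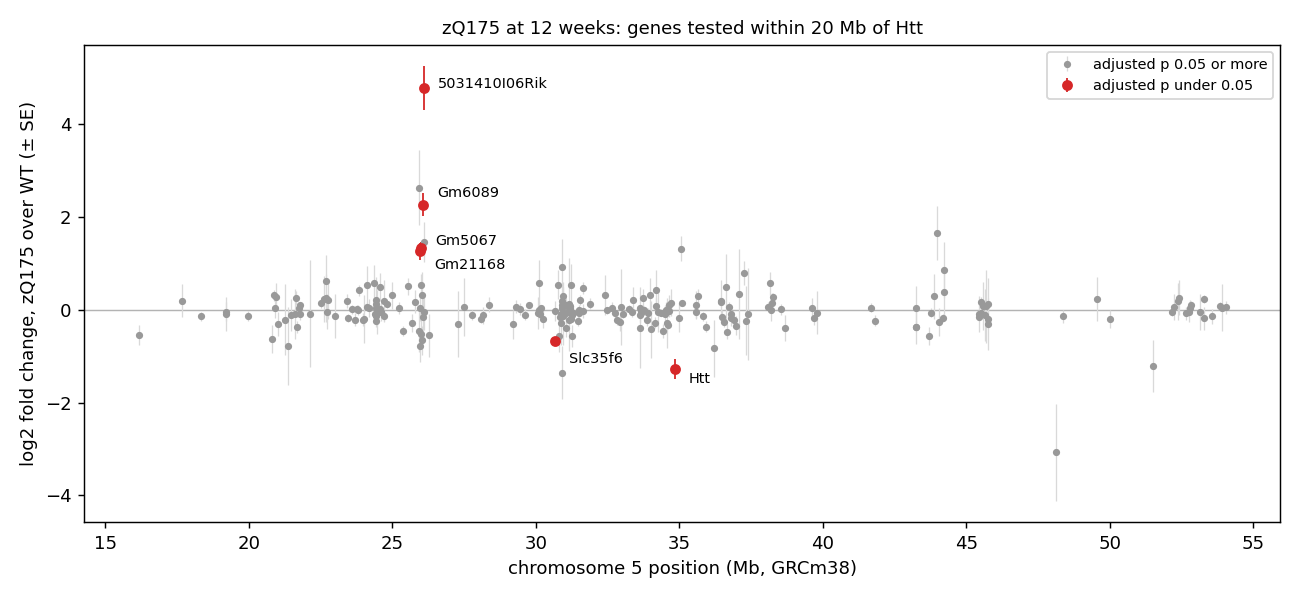
Log2 fold change of zQ175 against wild type at 12 weeks for genes tested around Htt, by position on chromosome 5 (Mb, GRCm38), with SE as bars and called genes in red. The called genes are Htt itself, at -1.27, Slc35f6, at -0.68, and the cluster near 26 Mb that includes 5031410I06Rik, at 4.78.

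The 1-year comparison asked whether the slower model came to resemble the faster one with age. Myelin genes were lower and progenitor genes higher in the means of zQ175 pools, but no gene of either list passed the test over all genes. Mbp was measured at 6420 ± 1030 CPM (SD, n = 5) against 9600 ± 2090 CPM (SD, n = 4), a log2 fold change of -0.53 ± 0.16 (adjusted p = 0.224). Myrf had a log2 fold change of -0.56 ± 0.18 (adjusted p = 0.247), and neither gene had overlapping groups. Pdgfra was measured at 30.1 ± 35.7 against 4.91 ± 7.5 CPM, a log2 fold change of 2.67 ± 1.18 (adjusted p = 0.433), and Tcf7l2 at 55.1 ± 16.7 against 46.7 ± 12.2 CPM (0.30 ± 0.25, adjusted p = 0.721). Both values rested in part on zQ175 replicate 2, with 93.1 CPM of Pdgfra and 84.6 CPM of Tcf7l2, and without it the log2 fold changes were 1.55 and 0.06 (adjusted p = 0.571 and 0.948). The Pdgfra value was 4.78 without wild-type replicate 3 (adjusted p = 0.0502), and passed with all 8 groups in 1 fit (2.58, adjusted p = 0.034), while that of Tcf7l2 was 0.12 without wild-type replicate 2 (adjusted p = 0.91).

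Of 14952 genes, 1 was called, and 1706 had an unadjusted p below 0.05. It was Gm42756 (ENSMUSG00000104674, chromosome 9, 109537100 to 109552780), an antisense transcript chosen after its values were seen, which fell by 1.34 ± 0.17 (adjusted p = 0.0391). The libraries do not record the strand, so its reads cannot be separated from those of a gene on the other strand. Of 24 mature myelin genes, 9 fell and 1 rose when adjusted over the list alone, and of 22 progenitor genes, 9 rose. Both lists passed camera with the preset correlation (adjusted p = 2.41e-06 and 6.95e-10) but not with an estimated correlation (adjusted p = 0.444 for both). The same was true of the interferon list, with a median of 0.97 (adjusted p = 0.00417, but adjusted p = 0.444 estimated), of cholesterol synthesis, here with a positive median of 0.26 (adjusted p = 0.00417, but adjusted p = 0.447 estimated), and of mitochondrially encoded mRNAs, with a median of -0.43 (adjusted p = 3.31e-05, but adjusted p = 0.444 estimated). Microglia, endothelial and mural markers had medians of -0.72, -0.88 and -0.84 beside these lists, with no member called (adjusted p = 0.000263, 0.0102 and 0.00358, and adjusted p = 0.444, 0.447 and 0.444 with an estimated correlation). Committed and premyelinating genes, receptors, extracellular matrix genes and pan-neuronal markers had positive medians of 1.05, 0.71, 0.85 and 0.98, also with no member called over all genes and, adjusted over the list alone, 5 matrix genes higher and 1 lower and 1 receptor lower. These 4 lists passed with the preset correlation (adjusted p = 0.000754, 0.00961, 0.000604 and 0.031) but not with an estimated one (adjusted p = 0.444 for each).

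The count at 1 year depended on the fit more than any other. By edgeR it was 0 without each library in turn (1269 to 1857 genes at an unadjusted p below 0.05), except that it was 233 without wild-type replicate 3. Wild-type replicate 4 and zQ175 replicate 5 had the fewest genes detected of all libraries, 15458 and 16476, and without both the count was 0. In wild-type replicate 4, 5.11% of counts were mitochondrial, against 3.3 to 3.62% in the other wild-type pools. DESeq2 called 393 genes, limma voom 312, the fit without a filter on low counts 59, and the fit of all 8 groups, which borrows its error from the other ages and the R6/2 line, 1718.

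The age-by-genotype interaction in the zQ175 line was past the threshold for 41 of 16535 genes, 12 in the positive and 29 in the negative direction. Rps12 and Rps21, ribosomal protein genes, had interactions of -1.37 and -1.36, and Hapln2, a link protein of the node of Ranvier, of -0.75. Map1b, a microtubule-associated protein of growing processes, Luzp2 and Cadm2, an adhesion gene, had interactions of 1.16, 1.47 and 0.96. All 10 called genes that the naming rule takes lost their call in some fits that left out 1 library. The edgeR count was 353 without wild-type 1-year replicate 3 and 110 without zQ175 1-year replicate 5. It was 11 or lower without zQ175 1-year replicate 2, 4 or 6, wild-type 1-year replicate 2, 4 or 5, wild-type 12-week replicate 2, 3, 4, 5 or 6, or any 12-week zQ175 pool. It was 0 with Y-linked transcripts as a covariate, where 1984 genes had an unadjusted p below 0.05, 327 with DESeq2 and 104 with limma voom. Htt, Tcf7l2 and Pdgfra had interactions of -0.10 ± 0.59, 0.44 ± 0.32 and 3.30 ± 1.38, none past the test, and without zQ175 1-year replicate 2 those of Tcf7l2 and Pdgfra were 0.21 and 2.18. Without wild-type 1-year replicate 3 that of Pdgfra was 5.34 (adjusted p = 0.0521). The progenitor and myelin lists passed with the preset correlation (adjusted p = 2.79e-09 and 0.000202) but not with an estimated one (adjusted p = 0.33 and 0.352). Of the same lists 10 progenitor genes were higher and 7 mature genes lower when adjusted over the list alone. In all, 8 lists passed with the preset correlation, 5 in the positive and 3 in the negative direction, and 0 with an estimated one.

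At 12 weeks the lines differed in their genotype effect. The line-by-genotype interaction, R6/2 effect minus zQ175 effect, was past the threshold for 3436 of 16223 genes, 1747 positive and 1689 negative. It was -0.80 ± 0.08 for Mbp (adjusted p = 5.98e-08), -0.49 ± 0.18 for Myrf (adjusted p = 0.0474), -0.63 ± 0.15 for Hmgcs1 (adjusted p = 0.00346) and 1.42 ± 0.31 for Htt (adjusted p = 0.00131). Of the other fixed genes, Sox10, Olig2 and Pdgfra did not pass, at -0.30 ± 0.20, -0.16 ± 0.12 and 0.44 ± 0.70 (adjusted p = 0.312, 0.384 and 0.707). Tcf7l2 had an interaction of 0.60 ± 0.22 and did not pass (adjusted p = 0.0509), but did in 8 of the 26 fits that left out 1 library. Of 24 mature myelin genes 22 had a negative interaction, of 16 interferon-stimulated genes 11 (14 adjusted over the list alone) a positive one, and of 11 sphingolipid genes 6 (7 adjusted over the list alone) a negative and 1 a positive one, and these 3 lists passed with an estimated correlation (adjusted p = 0.000193, 0.000193 and 0.0298). Cers2, a ceramide synthase, had an interaction of -0.77 and Rtp4 of 3.84. Of 22 progenitor genes, 13 (14 adjusted over the list alone) had a positive interaction (adjusted p = 7.98e-07, but adjusted p = 0.263 with an estimated correlation), and of 13 fibroblast markers 8 (10 adjusted over the list alone) a negative one (adjusted p = 7.58e-06, but adjusted p = 0.263 estimated). In all, 10 lists passed with the preset correlation, 5 in each direction.

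The last comparison asked which genes were called in both R6/2 at 12 weeks and zQ175 at 1 year. Only Gm42756, chosen after its values were seen, was called lower in both, where 0.2 would be by independent lists. Of the 5451 R6/2 calls tested at both, 4133 (75.8%) had the same sign at 1 year in zQ175, and the log2 fold changes correlated across genes with r = 0.50 and rho = 0.43. Against zQ175 at 12 weeks, 58.1% of the 12-week R6/2 calls had the same sign and r was 0.04, while of the 6-week R6/2 calls 80.7% had the same sign in zQ175 at 12 weeks (r = 0.13, rho = 0.22) and 86.5% at 1 year (r = 0.30, rho = 0.30). These shares were not tested against each other. These comparisons share no library, but genes are not independent replicates and no p is given. The shared count was 334 with DESeq2 and 215 without wild-type 1-year replicate 3.

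Age differences in wild-type mice give the background to these effects. From 6 to 12 weeks in the R6/2 line, 3782 of 14912 genes were called, 1825 higher and 1957 lower at 12 weeks. The myelin genes Ppp1r14a and Cldn11 fell by 1.07 and 0.87 on the log2 scale, with 15 of 24 mature genes lower and 1 higher (16 and 2 adjusted over the list alone; adjusted p = 9.82e-11, and adjusted p = 0.0154 with an estimated correlation). Of 20 cholesterol enzymes 15 fell (16 fell and 1 rose adjusted over the list alone), among them Sqle by 1.13 (adjusted p = 6.48e-14, but adjusted p = 0.059 with an estimated correlation). Of 20 committed and premyelinating genes 9 fell (11 adjusted over the list alone; adjusted p = 0.000842, but adjusted p = 0.856 with an estimated correlation). Beside these, 4 of 14 endothelial, 2 of 13 fibroblast, 1 of 11 mural and 1 of 16 microglia markers were higher at 12 weeks (6, 2, 1 and 1 adjusted over the list alone), among them Acta2, an actin of mural cells, by a log2 fold change of 1.86. These 4 lists did not pass camera (adjusted p = 0.0507 for endothelial markers and 0.216 for the others), and 2498 genes were called with markers of other cell types as a covariate. Htt was 2.46-fold higher at 12 weeks (adjusted p = 0.000455). Tcf7l2 fell by 0.58 ± 0.16 (adjusted p = 0.0149), a call lost with Y-linked transcripts or markers of other cell types as a covariate (adjusted p = 0.0566 and 0.268). Age here cannot be separated from the difference in the share of whole values between the libraries of the 2 ages.

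From 12 weeks to 1 year in the zQ175 line, 5931 of 14888 genes were called, 2744 higher and 3187 lower at 1 year. Of 20 cholesterol enzymes 13 fell, among them Hmgcs1 by 1.89 ± 0.17 and Cyp51 by 1.41 ± 0.13, and Ugt8a fell by 1.37, while Apoe, a lipid carrier, and Npc1, a lysosomal cholesterol transporter, were higher by log2 fold changes of 1.47 and 1.80. Tcf7l2 was higher, with a log2 fold change of 1.16 ± 0.21 (adjusted p = 0.000843). Markers of other cell types rose with these: of 13 fibroblast markers 11, of 11 mural markers 6 (7 adjusted over the list alone), of 15 microglia markers 9 (10 adjusted over the list alone) and of 14 endothelial markers 7, with 1 endothelial marker lower. The mitochondrial share of counts was 2.5 ± 0.44% (SD, n = 6) at 12 weeks and 3.87 ± 0.84% (SD, n = 4) at 1 year, a difference not tested by itself, and 10 of 13 mitochondrially encoded mRNAs were higher at 1 year (11 adjusted over the list alone; adjusted p = 0.000225, but adjusted p = 0.588 with an estimated correlation). None of the 9 lists that passed camera did so with an estimated correlation (adjusted p of 0.588 for cholesterol synthesis and 0.61 for endothelial markers, the highest). By fry 14 lists passed in this comparison. With markers of other cell types as a covariate, 1905 genes were called.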

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

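The tests of a lower oligodendrocyte share, of a common change in that share, of more microglia, of linked alleles and of shared gene copies were chosen only after the result was seen.

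In R6/2 pools at 12 weeks myelin genes were lower and progenitor genes higher. A smaller share of oligodendrocytes that raised all other cell types alike is argued against, since 54 microglia, endothelial, mural and fibroblast markers had a median log2 fold change of -1.14 (95% bootstrap interval over genes -1.31 to -0.96). That interval does not measure the spread between pools, and markers of a list move together. These lists did not pass camera with an estimated correlation. The argument therefore rests on the single markers, of which several per list were called lower and none higher. It covers only a share that raises the other cell types. The myelin list fell by a similar amount, with a weighted mean log2 fold change of -1.01. A larger share of progenitors could lower both, so a smaller share of oligodendrocytes in that form stays open. The mix of sexes as the whole cause is argued against as well, since with Y-linked transcripts as a covariate the progenitor list had a camera adjusted p of 1.42e-05 and the myelin list of 1.91e-29. Both are from the preset correlation, and without the covariate the progenitor list's call was lost with an estimated one (adjusted p = 0.405), so for that list the argument is weaker. A common change in share as the whole cause of the myelin fall stays open: the 24 members ranged from -1.85 for Mal to 0.22 for Apod, with a spread of 0.49 beyond their standard errors, but other cells also express some members. A change of gene expression within cells, a sort that took up more progenitors and a batch that follows genotype may each contribute and were not tested.

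In R6/2 pools at 6 and 12 weeks interferon-stimulated genes were higher. More microglia or macrophages as the cause is argued against, since their markers had a median log2 fold change of -0.11 at 6 weeks (interval over genes -0.42 to -0.01) and of -0.95 at 12 weeks (-1.12 to -0.76). These intervals do not measure the spread between pools. At 12 weeks several of the markers were called lower and none higher. At 6 weeks none was called, so the argument is weaker there. The rise did not rest on a single library: over 25 libraries left out in turn the largest camera adjusted p was 2.08e-14. With Y-linked transcripts as a covariate the larger adjusted p was 9.82e-18, which argues against the mix of sexes as the whole cause. Both p values are from the preset correlation, under which the other splits passed a median of 7 lists at 6 weeks and 9 at 12 weeks. Passing that test alone therefore decides little. In the main fits, without a covariate, the list also passed with an estimated correlation at both ages. A response of the sorted cells to the transgene or to interferon in the diseased striatum may be a candidate explanation, and was not tested. The marker medians bear on how many microglia or macrophages were present. In which cells of the pools the interferon-stimulated genes were higher cannot be told from them.

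In zQ175 pools at 12 weeks 5 of the 11 called genes other than Htt lay within 20 Mb of it. With genes less than 1 Mb apart counted once, 2 of 8 places did (Fisher's exact test, two-sided p = 0.00728), which is consistent with alleles carried along with the knock-in. Of the 5 genes, 4 are pseudogenes or unnamed models against 14.4% of all genes tested (Fisher's exact test, two-sided p = 0.00191). These 4 genes lie in 1 cluster and are not independent draws, so this p cannot decide the question. Reads shared between near-identical copies may also shape the cluster near 26 Mb. A difference of the 12-week libraries alone cannot be told apart from these: 4 of the 5 genes had the same sign at 1 year, but with a median absolute log2 fold change of 0.25 against 1.33. Slc35f6 went from -0.68 ± 0.09 to -0.17 ± 0.17 and Gm5067 from 1.33 ± 0.13 to 0.25 ± 0.32. Both were smaller at 1 year by more than these errors, although they had been selected at 12 weeks. 5031410I06Rik stayed higher, with a wide error (2.32 ± 1.02). An effect of lower Htt on its neighbours was not tested.

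Some libraries lay apart from the others of their group by the ratio of their gap to the group's range, in 21 of 240 pairs of a group and a measure. Chance gives about 1 in 20 such pairs, and many of the measures move together in the same libraries. R6/2 12-week replicate 7 was lowest for Htt (gap ratio 0.58), Pdgfra (0.78), Sox10 (0.68) and the extracellular matrix list (0.61), and highest for the mitochondrial share of counts (0.68). R6/2 6-week replicate 1 was highest for the mitochondrial share (0.8) and for mitochondrially encoded mRNAs (0.65), and R6/2 12-week replicate 3 was highest for Hmgcs1 (0.58). Among wild-type pools of the R6/2 line, 6-week replicate 4 was lowest for Htt (0.76) and replicate 3 lowest for the mitochondrial share (0.79). The 12-week replicate 6 was lowest for the fatty acid list (0.66) and highest for the interferon list (0.68).

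In the zQ175 line, zQ175 1-year replicate 2 was highest for Tcf7l2 (0.78) and lowest for the interferon list (0.73), and replicate 4 was lowest for mitochondrially encoded mRNAs (0.71). Wild-type 1-year replicate 4 did not pass the limit for any of these measures, but lay far from its group in principal components 3 and 4 of log2 CPM over all libraries (-121 and 130.2, against -13.5 to 6.9 and -47.1 to 3.7). Wild-type 1-year replicate 3 was lowest for the mature myelin list (0.99), at a mean log2 CPM of 10.81 against 11.02 for the nearest. The highest zQ175 1-year pool was at 10.79. On principal component 2 this wild-type pool lay at 77.5, near the zQ175 1-year pools (79.9 to 109.6). The other wild-type 1-year pools lay at 7.3 to 26.6. Without this pool 233 genes were called at 1 year. At 12 weeks zQ175 replicate 2 was lowest for that list (0.7), replicate 4 lowest for neuroblast markers (0.74), and replicate 3 lowest for pan-neuronal markers (0.78) and for the share of counts in the top 10 genes (0.64). Wild-type 12-week replicate 5 was highest for mitochondrially encoded mRNAs (0.85).

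Effects that differed between ages or lines by an interaction test were also noted. Between ages of R6/2 996 genes did, with Sox10 at -0.48, Mbp at -0.29 and the median of the mature myelin list at -0.55. Between ages of zQ175 41 genes did. Between lines at 12 weeks 3436 genes did, with Htt at 1.42, Myrf at -0.49, Mbp at -0.80, Hmgcs1 at -0.63, and list medians of -0.57 for sphingolipid synthesis, -0.88 for mature myelin genes and 2.82 for interferon-stimulated genes.

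Other splits of the same libraries, 100 for each result with the real one included, showed which counts were larger than relabelled libraries gave. As many calls came from 1 split, the real one, for R6/2 at 6 weeks (695, highest other 97) and at 12 weeks (5704, highest other 1), zQ175 at 12 weeks (12, highest other 1), and the line difference (3436, highest other 4). The same held for wild-type age in the R6/2 line (3782, highest other 1) and in the zQ175 line (5931, highest other 10) and the age difference of R6/2 (996, highest other 775). For zQ175 at 12 weeks this covers the count as a whole and not each gene. Apart from Htt, 5 of its calls lay within 20 Mb of Htt, and no call was left without chromosomes 5, X and Y. For the gene shared by R6/2 at 12 weeks and zQ175 at 1 year (1 split, the real one, with 1 gene, highest other 0) the test decides nothing, since both comparisons called a gene in 0 of the 99 other splits. Chance cannot be excluded for zQ175 at 1 year, where 7 splits called as many (1, highest other 15), for the age difference of zQ175, where 5 did (41, highest other 362), or for the number of lists past camera with the preset correlation, where 25 did (35, highest other 47). Taken singly, as many lists came from 61 splits for R6/2 at 6 weeks (7 lists) and 14 at 12 weeks (15 lists). For zQ175 they came from 97 splits at 12 weeks (1 list) and 9 at 1 year (12 lists). For the differences between ages or lines these splits also remove the genotype effects, so they test for no effect at all and not for equal effects. The split with 362 calls kept all 1-year labels and relabelled 8 of 12 libraries at 12 weeks, and that with 775 relabelled 8 of 11 libraries at 6 weeks and 2 of 14 at 12 weeks, so both kept most of the genotype labels at the older age.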

How the results depend on the processing

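The fits without libraries that stand apart and with markers of other cell types were chosen only after the data were seen. The counts for R6/2 at 12 weeks stayed within 1.5 times 5704 under every alternative run. For the values that follow the cause was not tested, except that a threshold of 0.01 leaves fewer calls by construction. With DESeq2 the counts were 1268 for R6/2 at 6 weeks, 442 and 393 for zQ175 at 12 weeks and 1 year, 327 for the zQ175 age difference and 334 shared genes. With limma voom they were 1163 for R6/2 at 6 weeks, 312 for zQ175 at 1 year, 1864 and 104 for the age differences of R6/2 and zQ175, and 269 shared. With all 8 groups in 1 fit they were 1718 for zQ175 at 1 year, 434 and 342 for the age differences, 2079 for the line difference, 2311 for wild-type age in the R6/2 line and 891 shared. With 1 surrogate variable they were 1363 for R6/2 at 6 weeks, 0 for zQ175 at 1 year, 1559 and 18 for the age differences and 0 shared. With Y-linked transcripts they were 34 and 0 for zQ175 at 12 weeks and 1 year, 0 for its age difference and 0 shared. At an adjusted p below 0.01 they were 239, 4, 0, 394, 0, 1836, 2132 and 3842 for R6/2 at 6 weeks, zQ175 at 12 weeks and 1 year, the age differences of R6/2 and zQ175, the line difference and wild-type age in the R6/2 and zQ175 lines, with 0 shared and 23 lists. DESeq2 size factors gave 2 for zQ175 at 1 year and 2 shared. No filter gave 59 for zQ175 at 1 year, 20 for its age difference and 56 shared. Without chromosomes 5, X and Y they were 0 and 3 for zQ175 at 12 weeks and 1 year, and 2 shared. Without libraries that stand apart they were 0 for zQ175 at 1 year, 1824 for the R6/2 age difference and 0 shared. The pools left out there were R6/2 6-week replicate 1 and 12-week replicate 7, wild-type 1-year replicate 4 and zQ175 1-year replicate 5. Wild-type 1-year replicate 3, which had the largest gap ratio, was kept. Without that pool alone 233 genes were called at 1 year and 215 were shared, so the result depends on which pools were left out. With markers of other cell types the counts were 3 for zQ175 at 1 year, 638 for the R6/2 age difference, 2498 and 1905 for wild-type age in the R6/2 and zQ175 lines, 2 shared and 21 lists.

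With the replicate block the counts were 224 for R6/2 at 6 weeks, 4 and 0 for zQ175 at 12 weeks and 1 year, 587 and 0 for the age differences and 0 shared, and they stayed within 1.5 times for R6/2 at 12 weeks (5397) and the line difference (3036). Same-numbered deviations correlated above 0.1 in 0 of 5, 2 of 7, 1 of 6 and 0 of 4 pairs of the genotype comparisons. No pairing by number was therefore seen, but so few pairs cannot show that same-numbered pools share no litter. What the numbers mark is not known. No block was fitted for wild-type age.

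Each library left out in turn gave 449 to 1008 calls for R6/2 at 6 weeks, 5167 to 7025 at 12 weeks, 4 to 11 for zQ175 at 12 weeks and 0 to 233 at 1 year. It gave 729 to 1784 and 0 to 353 for the age differences of R6/2 and zQ175, 2990 to 4723 for the line difference, 3175 to 3673 and 5174 to 5957 for wild-type age in the R6/2 and zQ175 lines, 0 to 215 shared and 32 to 39 lists.

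Directions turned only with markers of other cell types as the covariate, which removes part of those markers' own change by construction. In R6/2 at 12 weeks these were the microglia, endothelial and mural lists (adjusted p = 0.411, 0.333 and 0.935), and mt-Atp8, mt-Co3, Csf1r, Tmem119, Tek, Cldn5, Esam, Acta2 and Hbb-bs (log2 fold changes of 0.04, 0.18, 0.04, 0.08, 0.05, 0.19, 0.32, 0.38 and 0.13). In the R6/2 age difference they were the mitochondrial, astrocyte, microglia, endothelial and mural lists (adjusted p = 0.661, 0.0488, 0.0488, 0.675 and 0.813). In wild-type age they were the progenitor list of the R6/2 line (0.0459), and the endothelial list (0.866) and Tagln (-0.34) of the zQ175 line. The R6/2 mature myelin, interferon, cholesterol and progenitor lists at 12 weeks kept their direction and call with the preset correlation (5.54e-33, 6.37e-22, 1.63e-06 and 0.00679), while the progenitor call did not hold with an estimated one in the fit without covariates (adjusted p = 0.405). The 1-year comparison had the widest spread between pools, with a biological coefficient of variation of 58.3% against 30.2% in R6/2 at 12 weeks, and the lowest totals.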

Other observations

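The enrichment of ribosomal protein genes was tested only after the result was seen.

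In R6/2 pools at 12 weeks more neurotransmitter receptor and potassium channel genes were called higher than lower in the sorted cells. Of 25 glutamate and GABA receptor genes, 13 rose and 4 fell (15 and 5 adjusted over the list alone): Gria2 and Grin3a, subunits of AMPA and NMDA receptors, had log2 fold changes of 2.63 and 2.58, and Grm3 fell by 1.64. The list passed camera with the preset correlation (adjusted p = 0.0283), but had adjusted p = 0.426 with an estimated correlation. Of 23 potassium channel genes, 13 rose and 5 fell (6 adjusted over the list alone; adjusted p = 0.108), among them Kcnd2 at 3.30 and Kcnj16 at 2.39, while Kcna1 fell by 1.15. Of 18 immediate early genes, which tissue dissociation also induces, 10 rose and 2 fell (adjusted p = 0.0303, but adjusted p = 0.561 with an estimated correlation), with Fos at 2.97 ± 0.36. Of 9 neuroblast markers 3 rose, among them Dcx at 2.75 (adjusted p = 0.0386, but adjusted p = 0.42 with an estimated correlation), and of 11 pan-neuronal markers 4 rose (adjusted p = 0.157). Markers of striatal projection neurons went both ways, with 3 of 12 higher and 4 lower (adjusted p = 0.802): Arpp21 and Penk had log2 fold changes of 3.36 and 2.62, and Adcy5 and Ppp1r1b fell by 1.42 and 1.22.

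Other lists were also tested at 12 weeks in R6/2. Of 13 Wnt pathway genes 7 fell and 2 rose (8 and 3 adjusted over the list alone; adjusted p = 0.021, but adjusted p = 0.134 with an estimated correlation), and Nkd1, a feedback inhibitor, fell by 1.27. Of 27 cell cycle genes 4 rose and 2 fell (adjusted p = 0.802), of 16 genes of the unfolded protein and integrated stress responses 2 rose and 5 fell (adjusted p = 0.596), and of 13 mitochondrially encoded mRNAs 2 fell (0 adjusted over the list alone; adjusted p = 0.151). Of 3 ependymal markers 2 fell (adjusted p = 0.0666), and the 5 sex-specific transcripts had a median of -1.61 with none called (adjusted p = 0.395).

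In the zQ175 line, ribosomal protein genes were chosen after their values were seen. Of the 41 genes whose zQ175 effect differed between 12 weeks and 1 year 18 encode ribosomal proteins, all with a negative interaction, where 0.21 would by chance (Fisher's exact test over 86 such genes tested, two-sided p = 2.13e-31). The 86 genes had a median log2 fold change of 0.3 at 12 weeks and of -0.46 at 1 year. The set was picked from these same calls, so the p is no independent support. As many calls came from 5 of 100 splits of the libraries, the real one included, and up to 362 from another. Genes are not independent replicates, these genes have many processed pseudogenes that share reads with them, and 0 of the 41 calls were left with Y-linked transcripts as a covariate, so the pattern describes these libraries.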
